A study of Escherichia coli with 10 samples.

How the data were processed

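RNA from Escherichia coli K-12 biofilms grown on glass wool was measured on 10 single-colour Affymetrix arrays, 1 for each combination of strain, medium, time and plasmid state. The labels pair the arrays by strain, medium and time into 5 pairs, each with 1 array of cells without plasmid and 1 of cells carrying R1drd19. The pairs are ATCC25404 in LB at 24 h, MG1655 in the medium labelled M9C glu at 24 h, and BW25113 in LB at 7 h, 15 h and 24 h. Per the labels, RNA was extracted with a Qiagen RNeasy kit and labelled with biotin.

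The deposited values are probe set signal intensity on a linear scale, and per the submitters' processing notes they were made with MAS5. Its version and settings are not given in the sources used here. The deposited intensities held no value below 0, and after the lowest and highest 2% of probe sets were left out, their mean was 500.01 to 500.07 on every array, so each array had been scaled to 1 target. The table holds 7312 probe sets. Of these, 22 are array controls and were left out, which leaves 7290.

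Probe sets were named from the locus tag in their identifier and the Entrez numbers of the platform annotation, through gene names of assembly ASM584v2. Both routes named the same gene for 4032 gene probe sets, the Entrez number alone named 88 and the locus tag alone 28. The routes differed for 1 probe set, 2 had several genes, 68 had no match, and 126 shared probe sets were not named. The 2886 intergenic probe sets and 59 phage or plasmid probe sets keep their identifiers, of which bla, traD, traI and trbH are called by the gene in them. The genome build behind the identifiers is not given in the sources used here, so no coordinates are printed.

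Signals were taken to log2(value + 203.3), where 203.3 is the 10th percentile of all values. Differences are on that scale, which understates the change of low probe sets. The 30% of probe sets with the lowest mean were left out before testing, which left 5103, of which 3563 carry a gene name. The main model was fitted over all 10 arrays with limma 3.58.1 in R 4.3.3, with pair and plasmid as terms and a trend in the prior variance. It leaves 4 residual degrees of freedom, with Benjamini-Hochberg adjustment at 0.05. Contrasts of pair means gave the effects of time, of medium with strain, and of strain; the plasmid effect in M9C glu against LB was tested on the 5 pair differences. The pair block follows from the labels, and arrays of 1 pair correlated with a median r of 0.83 over probe sets, against 0.77 for arrays of different pairs. No arrays held identical values (0). With 1 array per group, the spread in these tests is that of the plasmid difference between strains, media and times. Nothing says whether any arrays share a culture, and single pairs were not tested on their own. The number of arrays limits the precision.

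Before the data were examined, 39 lists of genes were fixed, each tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated one. A gene with several probe sets was represented by the one with the highest mean. The list of conjugative plasmid genes was tested through bla, traD and traI. The array holds 8 other F plasmid probe sets, trbH among them, which were not entered in it. The heat shock list held rnlA, under an older name, by mistake; it is not a heat shock gene. List means over the 5 pairs were also tested with an exact two-sided sign-flip test, whose smallest possible p with 5 pairs is 0.0625. Within a pair, a list's median was set against 10000 random lists matched on mean signal.

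The genes named in the text follow a rule fixed beforehand. For the plasmid effect it takes 12 genes up and 12 down that pass the test with the same direction in all 5 pairs, filled by the smallest p where too few pass. For time, medium and strain it takes up to 8 each way among those that pass. For each pair it takes the 5 largest differences each way above the median signal, for each list described the 4 members with the largest difference, and always a fixed set of stress, biofilm and strain marker genes. Other names are said to have been chosen after their values were seen.

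On simulated data for the plasmid comparison with 200 changed probe sets among 5103, the model recovered 95.5% of those changed by 1 on the log2 scale, 100.0% of those changed by 2 and 98.5% of those changed by 3, with 14 false calls. So many changed probe sets loosen the adjusted threshold, so these shares do not carry over to data with few changes. In the real data the probe set insA_2 differed by 1.62 and was not called (limma adjusted p = 0.24). In simulated independent genes for the same comparison, 10 of 200 random lists of 20 among 3538 genes had an unadjusted p under 0.05 and 20 of 20 lists shifted by 0.5 were called. Alternatives were a pseudocount of 1 or of the median of all values (451.8), no filter or a 50% filter, quantile normalization, a median shift, each pair left out, a single prior variance, no pair block, subsets of pairs, and for lists an estimated correlation or the mean of all probe sets. Fits without the arrays in doubt, and a pseudocount of 1 without a filter, were added after the data were seen. So were a fit of ATCC25404 24 h and BW25113 15 h and 24 h, and quantile normalization with the 4 LB pairs. The estimated correlation for time, medium and strain was added then as well. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.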

Results

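Transcript levels were measured in E. coli K-12 biofilms on glass wool with and without R1drd19, a derepressed conjugative plasmid of the R1 family, which resembles the F plasmid in its transfer genes and carries ampicillin resistance. The 10 arrays form 5 pairs of 1 array without and 1 with the plasmid: ATCC25404 and BW25113 in LB at 24 h, MG1655 in M9C glu at 24 h, and BW25113 in LB at 7 h and 15 h. The design asks how carriage of the plasmid changes the transcriptome of biofilm cells, and the pairs also differ in time, medium and strain. No group has a replicate array. The median signal per array lay between 387.5 and 484.7. Intergenic probe sets had medians of 199.9 to 408.1, against 474.5 to 531.4 for gene probe sets. The gap was widest in BW25113 at 7 h with R1drd19 (199.9 against 519.8). By contrast, 27 probe sets for foreign sequences (phage, viral and vector controls) had medians of 3.70 to 28.0. Differences of weakly expressed genes are therefore measured on top of a floor near the intergenic level.

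**Figure D1:**
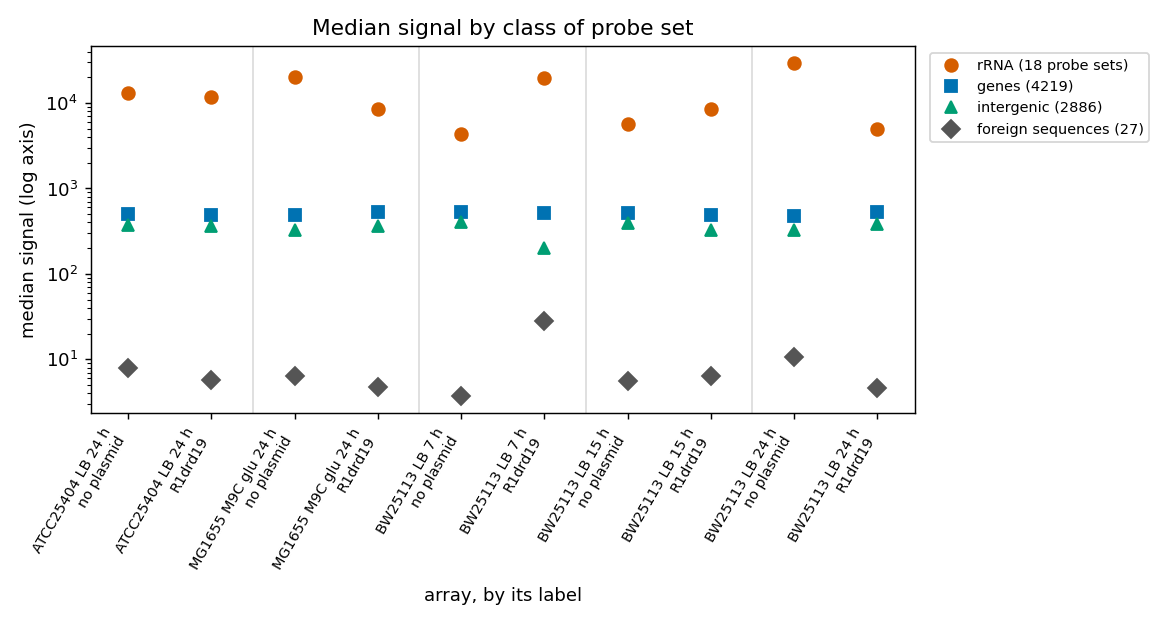
Median signal of rRNA, gene, intergenic and foreign probe sets on each array (log axis, 1 point per array and class, no replicates), in the order of the 5 pairs. Intergenic medians lie below gene medians on all 10 arrays and 7.14 to 110.3 times above the foreign medians.

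The plasmid label was borne out by the array's own plasmid probe sets. The signal of bla, the β-lactamase gene that gives ampicillin resistance, was 7.40 to 17.2 on the 5 arrays without plasmid and 2485 to 5358 on the 5 with R1drd19. The traD gene, for the coupling protein of conjugation, read 2514 to 4989 with R1drd19 and 7.30 to 22.1 in the 3 BW25113 arrays without it. It already read 641.6 in ATCC25404 without plasmid and 552.0 in the array labelled MG1655 without plasmid. The same 2 arrays read 823.8 and 1081 for traI, the relaxase gene. There, and in ATCC25404 with R1drd19, 8 other F plasmid probe sets (trbH among them) had medians of 843.4, 679.2 and 1132, against at most 29.8 on the other 7 arrays.

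Strain markers fitted the BW25113 labels and set 1 array apart. BW25113 lacks the arabinose and rhamnose genes araBAD and rhaDAB and part of lacZ. In its 6 arrays araA read 12.5 to 101.1, araB 16.2 to 131.7, rhaA 36.9 to 146.7 and rhaB 81.4 to 134.5. In the other 4 arrays these genes read at least 428.4, 364.6, 380.9 and 428.9 respectively. The probe sets for araD (473.3 to 842.6 in BW25113) and rhaD (543.5 to 954.4) were not low in BW25113. lacZ read 404.3 to 662.2 in BW25113, near the 550.6 of MG1655 with R1drd19. It was higher in ATCC25404 without and with R1drd19 (2082.9 and 3673.1) and in the array labelled MG1655 without plasmid (2551.4). Where the araD, rhaD and lacZ probe sets lie relative to the deletions was not examined. The 17 probe sets of the e14 prophage had medians of 178.5 to 458.9 in BW25113 and 430.1 in MG1655 with R1drd19. They had medians of 7.30 and 7.40 in ATCC25404 and 24.6 in the array labelled MG1655 without plasmid. That array thus carried F signals and lacked e14 signals, as ATCC25404 did and its partner did not, so these markers differ between the 2 arrays labelled MG1655. Every difference within the M9C glu pair, and every contrast of medium, rests on it in part.

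**Figure D2:**
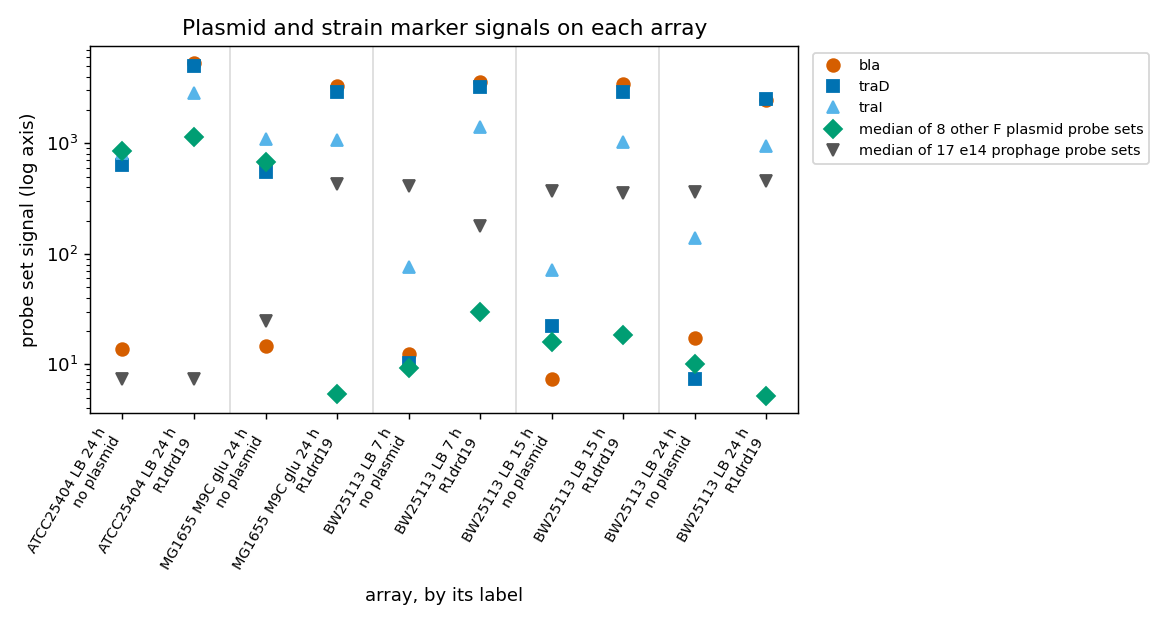
Signals of bla, traD and traI and medians of 8 other F plasmid probe sets and of 17 e14 probe sets on each array (log axis, 1 point per array, no replicates). bla separates the arrays by plasmid label in all 5 pairs, while F and e14 signals place the array labelled MG1655 without plasmid beside ATCC25404.

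Over the 5 pairs, bla and traD rose, and neither traI nor any chromosomal gene passed the test. bla rose by 4.11 ± 0.16 on the log2 scale (SE, 5 pairs, limma adjusted p = 6.24e-07) and traD by 3.22 ± 0.28 (adjusted p = 0.00096), both in 5 of 5 pairs. No probe set fell (0 calls), and 219 of 5103 had an unadjusted p under 0.05, where 255 would be expected by chance. traI differed by 1.60 ± 0.30 (adjusted p = 0.24). Its differences were 1.56 to 2.52 in the 4 LB pairs and -0.01 in the M9C glu pair, and it passed when only the 4 LB pairs were fitted (1.996 ± 0.18, adjusted p = 0.000749). In the M9C glu pair the array labelled without plasmid carried F signals and read 1081 for traI, against 1074 with R1drd19. With a pseudocount of 1, 0 probe sets were called although the differences were larger: bla (7.09 to 8.68 in the 5 pairs) fell under the filter and was not tested, and traD (5.74 ± 0.83, adjusted p = 0.26) spread from 2.39 to 8.24. Without the filter as well, an alternative chosen after seeing the data, bla was called (8.01 ± 0.28, adjusted p = 3.60e-06). With a single prior variance 5 probe sets were called.

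A total of 5 probe sets differed at least 2-fold in the same direction in every pair: bla, traD and 3 shared probe sets of insA. The insA gene belongs to the insertion sequence IS1 and has several copies in the genome, which these probe sets cannot tell apart. Whether R1drd19 carries copies as well was not examined, so the differences need not come from the chromosome. The insA probe sets were chosen after their values were seen. Their differences were 1.59 ± 0.32 for insA_1, 1.62 ± 0.28 for insA_2 and 1.51 ± 0.28 for insA_5 (SE), with adjusted p = 0.39, 0.24 and 0.24. All 3 passed with a single prior variance (adjusted p = 0.00703, 0.00236 and 0.00236), and insA_2 also passed without a filter (adjusted p = 0.0475).

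No chromosomal gene passed, and those named here were taken by smallest p among genes with the same sign in 5 of 5 pairs, so that sign was set by the choice. rne, for ribonuclease E, differed by 0.64 ± 0.12 (adjusted p = 0.24; 0.51 to 0.71 in the 5 pairs) and uhpA, a regulator of hexose phosphate uptake, by 0.48 ± 0.11 (adjusted p = 0.66). The other 8 genes with higher means had an adjusted p of 0.81 or more: sdhB of succinate dehydrogenase (0.56), the DNA-binding protein gene hupB (0.63), the leucine tRNA leuZ (0.44), lspA (0.41), ucpA (0.40), pxpC (0.39), the DNA polymerase IV gene dinB (0.33) and mukE (0.32). Among the lower means, pqqL stood at -0.45 ± 0.10 (adjusted p = 0.66). The other 11 had an adjusted p of 0.91: ybeD (-0.62), yebW (-0.50), the small RNA gene spf (-0.49), dicA (-0.40), yeeL (-0.36), yncI (-0.35), yccE (-0.33), mobB (-0.30), ydfI (-0.30), nadC (-0.29) and ygcE (-0.26). In all, 300 probe sets, or 5.88%, had the same sign in all 5 pairs, where chance gives 6.25%.

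Biofilm and stress genes fixed beforehand did not pass either. The phage shock gene pspA differed by 0.49 ± 0.43 (higher in 4 of 5 pairs), the Cpx-controlled cpxP by 0.37 ± 0.52 (2 of 5), spy by -0.10 ± 0.25 (3 of 5), the periplasmic protease gene degP by 0.34 ± 0.16 (3 of 5) and rpoE by -0.36 ± 0.29 (2 of 5). The curli subunit gene csgA differed by -0.20 ± 0.11 (0 of 5), the type 1 fimbrial subunit fimA by 0.26 ± 0.15 (4 of 5) and flagellin fliC by 0.14 ± 0.12 (4 of 5). Tryptophanase tnaA differed by 0.69 ± 0.39 (4 of 5), recA by 0.35 ± 0.21 (4 of 5), rpoS by 0.27 ± 0.32 (3 of 5), lacZ by -0.18 ± 0.32 (2 of 5), araD by -0.08 ± 0.14 (1 of 5) and rhaD by 0.11 ± 0.11 (3 of 5). All had an adjusted p of 0.91 or more. The means of tnaA and recA rest largely on the BW25113 pair at 7 h (3.11 and 1.31). Their differences were -0.08 to 0.21 and -0.17 to 0.32 in the other pairs. The antigen 43 gene flu lay under the filter, at signals of 226.0 to 450.2.

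Lists of aerobic energy metabolism had positive means with R1drd19, highest in BW25113 at 7 h and 15 h. With the preset correlation camera called them upward, and with an estimated correlation it did not (adjusted p = 0.83 with an estimated correlation for each). The 15 measured TCA cycle genes averaged 0.52 ± 0.76 (SD of 5 pairs), and in none was the mean lower (0). Their largest differences were sdhA (0.83), sucB (0.76), aceB (0.64) and sdhC (0.60). The pair means were 1.53 at 7 h and 1.05 at 15 h, against -0.36 in BW25113 at 24 h, 0.34 in ATCC25404 and 0.05 in the M9C glu pair. Adjusted over the list alone, 1 member passed, sdhB (adjusted p = 0.0149), and over all genes 0. The 19 genes of the aerobic respiratory chain (NADH dehydrogenases I and II and cytochrome bo oxidase) averaged 0.39 ± 0.56, with nuoE (0.70), nuoC (0.67), nuoI (0.55) and nuoL (0.52) in front. Their pair means were 1.33 and 0.43 in BW25113 at 7 h and 15 h, against -0.06 in BW25113 at 24 h, 0.17 in ATCC25404 and 0.08 in the M9C glu pair. The 9 ATP synthase genes averaged 0.37 ± 0.79, with atpF (0.65), atpB (0.54), atpH (0.51) and atpE (0.46). Their pair means were 1.68 and 0.50 in BW25113 at 7 h and 15 h, against -0.24 in BW25113 at 24 h, -0.12 in ATCC25404 and 0.02 in the M9C glu pair. The R1drd19 array at 7 h stood apart: it correlated with the other 9 arrays at r 0.48 to 0.70, and its rRNA signal was 4.58 times that of its partner. Under quantile normalization the 7 h means were 0.72 for the TCA cycle, 0.80 for the respiratory chain (1.33 as deposited) and 1.02 for ATP synthase, and the TCA mean in BW25113 at 24 h was -0.10. With only the 3 pairs at 24 h the ATP synthase mean turned to -0.12, and the calls of all 3 lists were lost; that of ATP synthase was also lost without the 7 h pair (mean 0.039, adjusted p = 0.98) and without the 15 h pair (mean 0.33, adjusted p = 0.11). Among respiratory chain and ATP synthase genes no member passed, over all genes or adjusted over the list alone (0).

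By camera with the preset correlation, 9 of 39 lists were called, 6 upward and 3 downward (5 without the BW25113 pair at 7 h, 15 with only the 3 BW25113 pairs). With an estimated correlation 0 lists were called: adjusted p = 0.12 for the plasmid genes and adjusted p = 0.83 for the other 8. Upward, with the preset correlation, these were the 3 plasmid genes (mean 2.97, adjusted p = 2.42e-12; 2 passing over all genes and 3 adjusted over the list alone), the TCA cycle (1.44e-06), the respiratory chain (1.29e-06), ATP synthase (0.0244), outer membrane proteins (mean 0.28, adjusted p = 0.0248) and osmotic and potassium genes (mean 0.19, adjusted p = 0.0407). Outer membrane members included lpp (0.79), ompC (0.78), nmpC (0.63) and ompA (0.63), and ompC also led the osmotic list, before ompR (0.29), ompF (0.27) and proP (0.27). Downward they were 30 cryptic prophage genes (mean -0.08, adjusted p = 0.000714), 19 toxin-antitoxin genes (mean -0.12, adjusted p = 0.00553) and 4 curli genes (mean -0.20, adjusted p = 0.0104). Of these, nmpC (0.63), yfjJ (-0.27), yfjM (-0.26) and intA (-0.25) had the largest prophage differences, mqsR (-0.55), mqsA (-0.47), yafQ (-0.40) and mazF (-0.27) the largest toxin-antitoxin differences, and the curli genes were csgB (-0.23), csgA (-0.20), csgC (-0.20) and csgF (-0.17). Exchanging the 2 arrays within pairs, in 16 ways with the real one, gave as many chromosomal lists in 11, and an exact two-sided sign-flip test gave p = 0.125 to 0.4375 for the 8. Under quantile normalization the calls of ATP synthase (adjusted p = 0.0527), toxin-antitoxin (adjusted p = 0.0926) and osmotic genes (adjusted p = 0.220) were lost. In BW25113 at 7 h the pair means were 0.77 for outer membrane, 0.63 for osmotic and -0.63 for curli genes. In the other pairs they ran from -0.07 to 0.50, -0.07 to 0.18 and -0.26 to 0.12 in that order.

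Envelope stress lists were not called. The 7 phage shock protein genes, a response to damage of the inner membrane, averaged 0.37 ± 1.10 (SD of 5 pairs; camera adjusted p = 0.38). Their mean was 0.76 in ATCC25404 and 0.41, 1.65 and 0.42 in BW25113 at 7 h, 15 h and 24 h, against -1.37 in the M9C glu pair, where the partner is the array in doubt. At 7 h their median lay above 52.7% of random lists matched on signal, so it did not stand out there. In the other LB pairs it lay above at least 99.7% of them. Under quantile normalization the list was called (mean 0.53, adjusted p = 0.0360; adjusted p = 0.91 with an estimated correlation). The leading members were pspD (0.60), pspE (0.49), pspA (0.49) and pspB (0.49). The 17 Cpx genes averaged 0.14 ± 0.32 (adjusted p = 0.20) with yccA (0.47) in front, and the 24 sigma E genes 0.04 ± 0.21 (adjusted p = 0.53), a mean that turned negative in 3 alternatives. The heat shock list averaged -0.09 ± 0.34 (adjusted p = 0.071) and was called under quantile normalization (mean -0.15, adjusted p = 0.00158; adjusted p = 0.64 with an estimated correlation). The lists not described here were not called with the values as deposited. Among them, 23 sigma S genes averaged -0.01 (adjusted p = 0.38), 52 ribosomal protein genes 0.16 (adjusted p = 0.16), 7 type 1 fimbriae genes -0.06 (adjusted p = 0.20) and 22 SOS genes 0.06 (adjusted p = 0.57).

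**Figure D3:**
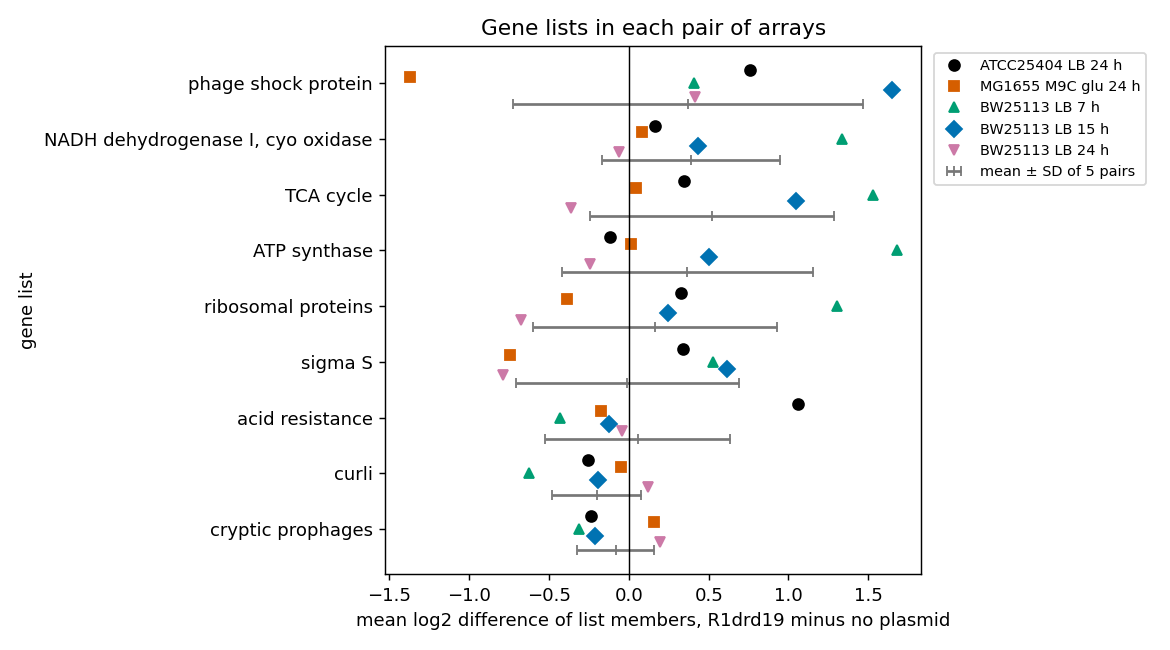
Mean log2 difference (R1drd19 minus no plasmid) of the members of 9 gene lists in each of the 5 pairs (coloured points, 1 pair of arrays each), with the mean ± SD of the 5 pairs in grey. The phage shock protein list lies at -1.37 in the M9C glu pair and between 0.41 and 1.65 in the LB pairs, and BW25113 at 7 h has the highest value in 4 of the lists.

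Within single pairs, which were not tested on their own, signals are given without and with R1drd19. In ATCC25404 at 24 h, the acid resistance genes hdeA (signal 493.2 without and 6086 with R1drd19), gadB (473.2 and 4338) and gadE (228.9 and 1916) were higher with the plasmid. The glycerol genes glpF (2270 and 437.7) and glpD (2243 and 447.4), the serine tRNA serV (2922 and 1016), bsmA (6722 and 2525) and rnlA (2172 and 796.9) were lower. The 16 acid resistance genes averaged 1.06 in this pair and -0.43 to -0.04 in the other 4. In the M9C glu pair the glycerol genes stood the other way: glpD read 488.6 in the array labelled MG1655 without plasmid and 3300 in MG1655 with R1drd19, glpF 481.8 and 3155, and glpK 239.7 and 1672. Lower with R1drd19 were yjbJ (10602 and 1921), the lipid A gene lpxC (8306 and 1492), yiaG (4170 and 865.0), lacZ (2551 and 550.6) and mcbA (2847 and 651.4).

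In BW25113 at 7 h, tnaA (650.8 without and 7194 with R1drd19), atpF (739.3 and 7643) and the chaperonin gene groS (1158 and 8541) were higher. Lower were gadB (3251 and 862.2), ydiH (971.6 and 322.9), mdlA (826.4 and 328.2), ydiZ (884.7 and 362.2) and the ribosomal protein gene rpmG (1280 and 656.4). The 52 ribosomal protein genes together went the other way from rpmG, with a mean of 1.30 in this pair. At 15 h the phage shock genes pspD (418.5 and 2895), pspB (848.7 and 4864) and pspA (599.0 and 3618) were higher. The glycine tRNA glyT (1798 and 901.7), gadA (2324 and 1343), the signal recognition particle RNA ffs (3205 and 2073), tsgA (852.8 and 507.9) and srlA (893.6 and 539.6) were lower. At 24 h the histidine tRNA hisR (442.0 and 1168), ydiT (462.5 and 930.6) and sgbE (432.8 and 859.6) were higher. Lower were the tmRNA gene ssrA (31449 and 4931), the RNase P RNA gene rnpB (8040 and 1490), the 6S RNA gene ssrS (17083 and 4562), the ribosome modulation factor gene rmf (19068 and 3860) and yjbJ (8800 and 1980). Under quantile normalization the difference of ssrS turned to 0.47 and that of rmf to 0.05, from -1.86 and -2.25.

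At least 2-fold differences numbered 43 upward and 11 downward in ATCC25404, 22 and 120 in the M9C glu pair, and 355 and 211, 84 and 17, and 13 and 163 in BW25113 at 7 h, 15 h and 24 h. Quantile normalization moved these to 40 and 18, 31 and 37, 62 and 118, 38 and 24, and 32 and 20. The direction of these counts thus turned with the scaling at 7 h and at 24 h in BW25113. The median shift gave a higher share of 71.5% at 7 h, against 62.7% as deposited and 34.4% under quantile normalization.

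For a plasmid effect that differs between M9C glu and LB, limma called 0 probe sets, with 104 at an unadjusted p under 0.05 (255 expected by chance). With 1 pair against 4 and a median SE of 0.35, this does not show that the effects were alike. The largest differences among the fixed genes were pspA at -2.33 ± 0.74 (SE, M9C glu pair minus the mean of the 4 LB pairs) and lacZ at -2.11 ± 0.42, both with an adjusted p of 0.99. The lacZ signal was high only on the arrays with F signals (2083 and 3673 in ATCC25404, 2551 in the array in doubt). Its difference therefore follows the markers that set that array apart. Only 1 pair was grown in M9C glu, in another strain and with the array in doubt, so medium, strain and label cannot be separated here. Without the BW25113 pair at 24 h, 4 genes were called, named here after their values were seen: rmf (-2.43), fbaB (-2.22), talA (-2.06) and ygaM (-2.02), each with an adjusted p of 0.0494.

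In BW25113 biofilms, averaged over both plasmid states, camera with the preset correlation called 8 gene lists lower at 24 h than at 7 h. ATP synthase and ribosomal protein genes were among them, and 3 lists, toxin-antitoxin, sigma S and curli genes, were called higher. With minus without R1drd19, ribosomal protein genes differed by 1.30 at 7 h and -0.68 at 24 h. TCA cycle genes differed by 1.53 and -0.36, ATP synthase genes by 1.68 and -0.24, and sigma S genes by 0.53 and -0.79. The ribosomal and TCA means therefore fell only with R1drd19, and the ATP synthase mean mainly there. The sigma S mean rose only without R1drd19. With an estimated correlation 0 lists were called (adjusted p = 0.68 for each of the 11), and without the R1drd19 array at 7 h all 8 lower lists and curli lost their calls. The lists of oxidative stress (adjusted p = 0.0534), phage shock (adjusted p = 0.136), SOS (adjusted p = 0.461), heat shock (adjusted p = 0.776) and acid resistance genes (adjusted p = 0.780) were not called. Under quantile normalization phage shock (mean 1.02, adjusted p = 0.0205) and oxidative stress genes (mean 0.19, adjusted p = 0.0334) were called, with adjusted p = 0.55 with an estimated correlation for both. The calls of osmotic (adjusted p = 0.0730), branched-chain amino acid (adjusted p = 0.0624) and curli genes (adjusted p = 0.0963) were lost there. limma called 0 probe sets between 24 h and 7 h (700 at an unadjusted p under 0.05), 0 between 15 h and 7 h (402) and 0 between 24 h and 15 h (341), with 255 expected by chance. tnaA had the largest time difference of the fixed genes, -2.25 ± 0.62 (SE, 24 h minus 7 h, adjusted p = 0.25) and -2.27 ± 0.62 (15 h minus 7 h, adjusted p = 0.60). It rests on the R1drd19 array at 7 h (7194) more than on its partner (650.8). fimA differed by -0.88 ± 0.23 between 24 h and 7 h (adjusted p = 0.24).

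Of these 11 lists among 39, the lower ones were 9 ATP synthase genes (mean -1.03, 7 passing adjusted over the list alone; atpF -1.74, atpH -1.61, atpA -1.45, atpG -1.14) and 19 respiratory chain genes (mean -0.73, 11 passing over the list alone; nuoE -1.29, nuoC -1.22). So were 15 TCA cycle genes (mean -0.74; sdhA -1.41 and aceA -1.29 did not pass, and sdhB, -0.82, was the 1 that did), 52 ribosomal protein genes (mean -0.59, 0 passing; rpsJ -1.501, rpsS -1.45) and 11 maltose genes (mean -0.52, 6 passing; lamB -0.97, malE -0.91). Further downward lists were 33 sugar transport genes (mean -0.44, 3 passing; the galactitol genes gatC -2.34, gatD -1.71 and gatB -1.47), 12 osmotic and potassium genes (mean -0.39, 1 passing; ompC -1.72) and 13 branched-chain amino acid genes (mean -0.30, 3 passing; ilvG -0.84, ilvN -0.71). Upward were 19 toxin-antitoxin genes (mean 0.43; relE 1.501, mqsR 1.30 and relB 0.99 among 5 passing upward over the list alone, with mazE, -0.78, passing downward), 23 sigma S genes (mean 0.40, 0 passing; yjbJ 1.62, bolA 1.20, kbp 1.14) and 4 curli genes (mean 0.35, 0 passing; csgF 0.44, csgC 0.42). Over all genes 0 members passed in any of these lists. Without the R1drd19 array at 7 h, which had the widest signal spread (SD 0.83 on the log2 scale, against 0.38 in its partner), 2 lists were called, sigma S (mean 0.73, adjusted p = 1.65e-05) and toxin-antitoxin (mean 0.35, adjusted p = 0.0155), with 1 array left at 7 h. Both were lost there too with an estimated correlation (adjusted p = 0.90 with an estimated correlation for both).

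Between M9C glu and LB at 24 h, 2 lists were called by camera with the preset correlation, acid resistance with a lower mean in M9C glu and sugar transport with a higher one. Both calls were lost with an estimated correlation (adjusted p = 0.99 with an estimated correlation for both). limma called 0 of 5103 probe sets (149 at an unadjusted p under 0.05). The 16 acid resistance genes averaged -0.54, with 11 lower and 5 higher (camera adjusted p = 0.00103; gadE -1.65, gadB -1.47, hdeA -1.43, hdeB -1.32), and the 33 sugar transport genes 0.29, with 25 higher and 8 lower (adjusted p = 0.0179; gatY 1.65, gatZ 1.41, gatA 0.96, glpF 0.82). In both lists 0 members passed, over all genes or adjusted over the list alone. Under quantile normalization TCA cycle genes were called as well (mean -0.21, adjusted p = 0.0282; adjusted p = 0.97 with an estimated correlation). Medium is joined to strain in this contrast, which also averages both plasmid states. With minus without R1drd19, acid resistance genes differed by 1.06 in ATCC25404, -0.04 in BW25113 at 24 h and -0.18 in the M9C glu pair. Their lower mean in M9C glu was therefore more marked with R1drd19 than without it. glpF read 481.8 in M9C glu and 2270 in ATCC25404 without plasmid, but 3155 and 437.7 with R1drd19. Without the array labelled MG1655 without plasmid, 15 lists were called, both of these among them (-0.69 and 0.30), together with phage shock genes (-0.83, against 0.26 with all arrays), TCA cycle genes (-0.51) and sigma S genes (-0.34, against 0.12), and 0 probe sets. These calls rest on 1 M9C glu array, and 0 lists remained with an estimated correlation (adjusted p = 0.89 with an estimated correlation for each).

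Between ATCC25404 and BW25113 in LB at 24 h, 3 lists were called by camera with the preset correlation: ribosomal protein genes with a lower mean in ATCC25404, and plasmid and Cpx genes with a higher one. All 3 calls were lost with an estimated correlation, with adjusted p = 0.91, adjusted p = 0.50 and adjusted p = 0.91 in that order. The contrast averages both plasmid states. With minus without R1drd19, ribosomal protein genes differed by 0.33 in ATCC25404 and -0.68 in BW25113 at 24 h. Their strain difference therefore lay almost wholly between the arrays without plasmid, whose rRNA medians were 13016 in ATCC25404 and 29730 in BW25113. The lacZ difference was 2.06 ± 0.51 (SE, ATCC25404 minus BW25113), traD 1.47 ± 0.45 and traI 1.49 ± 0.47, none of them passing over all genes (adjusted p = 0.9999 for each), and limma called 0 probe sets (64 at an unadjusted p under 0.05). Without R1drd19, traD and traI already read 641.6 and 823.8 in ATCC25404, which carried F signals, against 7.30 and 139.0 in BW25113. bla differed by 0.51 and did not pass. The call of the plasmid genes is therefore not one of R1drd19 genes alone. The 3 lists were 52 ribosomal protein genes (mean -0.55, 0 passing over all genes or adjusted over the list alone, camera adjusted p = 1.72e-13; rplR -1.09, rpsN -1.06, rplD -1.05, rpsP -1.04), the 3 plasmid genes (mean 1.16, adjusted p = 7.09e-06; traD and traI passing adjusted over the list alone, adjusted p = 0.0108), and 17 Cpx genes (mean 0.26, adjusted p = 0.00493; yebE 0.99, htpX 0.76, cpxP 0.61, degP 0.45). A fit of the 4 LB arrays at 24 h alone, with 1 residual degree of freedom, called 22 probe sets.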

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

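All tests of explanations below were chosen only after the results were seen.

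The 8 F plasmid probe sets that are not traD or traI had medians of 843.4 and 1132.2 in ATCC25404 without and with R1drd19 and 679.2 in the array labelled MG1655 without plasmid, against at most 29.8 on the other 7 arrays; they enter no comparison. The pattern weighed is that this last array carries F and lacks e14. A difference in expression alone is argued against, since its e14 median was 0.0745 of its intergenic median, far under the intergenic level. An exchange of labels between 2 arrays of the series is argued against, since 0 arrays labelled ATCC25404 or BW25113 were out of place. RNA of another strain in this array stays open: 96.0% of the 25 F and e14 probe sets lay closer to ATCC25404 than to the partner array, which restates the pattern, and over all tested probe sets r was 0.80 and 0.86 with the ATCC25404 arrays and 0.85 with the partner. An MG1655 stock with F and without e14 would look the same and was not tested.

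The 7 phage shock protein genes averaged -1.371 (log2, R1drd19 minus no plasmid) in the M9C glu pair and 0.81 over the 4 LB pairs, where each pair was positive (0.41 to 1.65). In BW25113 at 7 h the list's median lay above only 52.7% of random lists matched on signal. The difference between media was not tested for the list, and the only M9C glu reference is the array in doubt.

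A floor near the intergenic level lies under most probe sets. Array background or nonspecific binding is argued against, because intergenic medians were at least 7.14 times the foreign medians on every array. Genomic DNA in the labelled sample stays open as a candidate explanation: in the 7 arrays that carry e14, the e14 median and the median of intergenic regions of at least 1000 bp agreed within 1.21-fold, while e14 medians were 7.30 to 24.6 on the other 3 arrays. Random labelling of low transcription across the genome was not tested. No biological explanation was tested.

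Abundant transcripts moved together within a pair, by medians from -1.002 in BW25113 at 24 h to 1.13 in BW25113 at 7 h (log2, 200 most abundant probe sets). Unequal shares of the floor in the 2 arrays stay open: in 5 of 5 pairs over 60% of these probe sets moved with the array's signal spread and the intergenic median the other way, but scaling every array to 1 trimmed mean ties these values together, so this decides nothing. A difference in growth state stays open as well. It was taken to move ribosomal protein and sigma S genes in opposite directions, whereas their means had the same sign in 5 of 5 pairs. But abundant members share the pattern, and against random lists matched on signal both medians lay on the same side in 3 pairs only. The signs therefore decide nothing here. Under quantile normalization the medians were -0.05 to 0.11. That scaling gives every array the same distribution of signals, so medians near 0 were set in advance and decide nothing. A change of total mRNA per cell with the plasmid stays open, untested.

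For the 2 probe sets called between arrays with and without R1drd19, 5 of 100 drawn splits of the 10 arrays (126 in all) gave as many, the real one included, with the highest other at 662. The other 4 all part only 1 pair, and those with 662 calls part BW25113 at 7 h; they read that pair's difference, which points to a structure of the samples and decides nothing on chance. Among the 16 splits that part all 5 pairs, 1, the real one, gave as many, with the highest other at 0; 16 splits are too few for a share under 0.05. For the 8 chromosomal gene lists called, 11 of the same 16 splits gave as many, with the highest other at 16, so chance is not excluded for the list calls.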

How the results depend on the processing

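The fits without arrays in doubt, the fit of pairs ATCC25404 24 h and BW25113 15 h and 24 h, quantile normalization with the 4 LB pairs, a pseudocount of 1 without a filter, and the estimated correlation for time, medium and strain were chosen after the results were seen. Of single-gene plasmid differences over all settings, 764 kept direction and side of the threshold, 9 gained a call, 3 lost one and 14 changed sign; of list means 159, 10, 38 and 7. Without the pair block 2 probe sets were called for the plasmid, and no call changed. Arrays with a high floor relative to signal limit what low genes can show. For values below that moved or changed sign, the cause was not tested unless given.

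With a pseudocount of 1, plasmid calls went from 2 to 0, since bla fell under the filter and traD, at 5.74 ± 0.83 against 3.22 ± 0.28, spread more between pairs (SD 2.85 against 0.85); without a filter as well, 1 was called, bla at 8.01 ± 0.28. With a pseudocount of 1, 2-fold counts went to 94 in ATCC25404 and 1211, 173 and 310 in BW25113 at 7 h, 15 h and 24 h. With the median as pseudocount, strain calls were 1 and the 7 h and 15 h counts 284 and 61. Without a filter, strain calls were 2 and strain lists 5. Under quantile normalization, calls were 5 (24 h against 7 h), 1 (15 h against 7 h), 1 (24 h against 15 h) and 1 (medium), 2-fold counts 68 in the M9C glu pair and 180, 62 and 52 in BW25113, and the 24 h differences of rmf and ssrS 0.052 and 0.47. One prior variance, and a 2-fold difference in all 5 pairs, each gave 5 plasmid probe sets.

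With only the BW25113 pairs, plasmid lists were 15 and lacZ 0.072. With only the 4 LB pairs, spy was 0.064 and lacZ 0.24, and lacZ was 0.12 with quantile normalization as well. With ATCC25404 24 h and BW25113 15 h and 24 h, spy was 0.0041 and lacZ 0.34. With only the 3 pairs at 24 h, plasmid calls were 1, and means were 0.038 for cryptic prophages, -0.12 for ATP synthase, -0.066 for phage shock, -0.081 for Cpx, -0.10 for sigma E, -0.18 for pspA, -0.45 for cpxP and -0.26 for rpoS. The fit of BW25113 arrays gave 1 call between 24 h and 7 h, that of 24 h arrays 6 medium lists, and that of LB 24 h arrays 22 strain calls and 6 strain lists. With an estimated correlation, lists were 0 for plasmid, 0 for time, 0 for medium and 0 for strain. Without the R1drd19 array at 7 h, calls between 24 h and 7 h were 1 and time lists 2; without the array labelled MG1655 without plasmid, medium lists were 15. Both list counts were 0 with an estimated correlation.

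Leaving out each pair in turn gave 2 to 3 plasmid calls, 0 to 2 calls between 24 h and 15 h, 0 to 4 for M9C glu against LB, 5 to 13 plasmid lists and 2 to 5 medium lists. The plasmid differences ranged from -0.020 to 0.11 for the sigma E list, -0.025 to 0.60 for cpxP, -0.25 to 0.071 for spy, -0.19 to 0.014 for araD and -0.41 to 0.24 for lacZ.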

Other observations

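No test is reported in this part, and all values here were chosen after the main results were seen. In MG1655 with R1drd19, otsA, for trehalose-6-phosphate synthase, and its neighbour uspC, for a universal stress protein, read at most 8.70. On the other 9 arrays otsA read 320.5 to 679.0 and uspC 300.6 to 488.1. Its operon partner otsB, for trehalose-6-phosphate phosphatase, read 1158 on that array and 726.1 to 2331 on the others. The array labelled MG1655 without plasmid read 679.0 and 409.6 for otsA and uspC, so the partners of the M9C glu pair differ here as well as in F and e14.

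Ribosomal RNA varied strongly between arrays. The median of 18 rRNA probe sets ranged from 4302 in BW25113 at 7 h without plasmid to 29730 in BW25113 at 24 h without plasmid. Within pairs, the R1drd19 array held 0.894 times its partner's rRNA signal in ATCC25404, 0.421 times in the M9C glu pair, and 4.58, 1.503 and 0.168 times in BW25113 at 7 h, 15 h and 24 h.

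Pair differences were correlated across probe sets for some pairs: r was 0.50 between BW25113 at 7 h and at 15 h and 0.51 between the M9C glu pair and BW25113 at 24 h, but -0.35 between BW25113 at 15 h and at 24 h. The signs of all these correlations followed the signal spread of the arrays. They were positive among ATCC25404 and BW25113 at 7 h and 15 h, where the R1drd19 array had the wider spread. The M9C glu pair and BW25113 at 24 h, where it had the narrower spread, also correlated positively. All other combinations were negative (-0.35 to -0.08). The values therefore cannot tell a shared plasmid response from that pattern. These correlations are across probe sets, which are not independent replicates.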
